A study of Mus musculus with 9 samples.

How the data were processed

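The samples are kidneys of mice profiled by RNA sequencing in 3 groups of 3 libraries each. The groups are a control group, a group with chronic kidney disease (CKD), and a group with CKD that also received a short hairpin RNA against the gene Galnt3, labelled CKD+sh-GALNT3. A short hairpin RNA is a small RNA meant to lower the level of its target transcript. The labels do not say whether the replicates of a group are separate animals, how the disease was induced, how the hairpin was delivered, or the sex of the mice. RNA came from a TRIzol extraction, per the labels' protocols. Those protocols describe a small-RNA library, whereas genes annotated as protein-coding held 92.2% to 93.4% of the counts of each library and small-RNA genes 0.0109% to 0.0187%, so the values were treated as messenger RNA.

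The deposited gene and transcript tables hold expected counts, meaning estimated reads, in 1 column per library, per the file headers. They are whole numbers and are not normalized. In every library, 100% of the transcripts with few counts lay between 0 and 1 above their length times their FPKM times a constant for the library, within a tolerance of 0.05, so the estimates had been rounded up per transcript. The gene counts of each library added up to the same total as its transcript counts. The second pair of deposited tables holds FPKM (fragment counts scaled by transcript length and library size) per gene and per transcript, per the file headers, and the denominator of the library scaling is not given in the sources used here. Coordinates are those of the tables, on the mouse build mm10 per the submitters' processing notes. The aligner, the quantification tool, their versions and the strand setting of the counting are not given in the sources used here. Every per-sample column was matched to its library by its title. Gene symbols came from the tables for 33992 of the 33994 genes with any count, and the remaining genes held 2 counts together.

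The depth was 51832755 to 64946105 counts per library. A gene with 0 counts in a library could still have had up to 3 counts, which is 0.0462 to 0.0579 CPM (counts scaled to the library size). Such floors and all 95% counting intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A fold against a group whose libraries were all at 0 is given as a lower bound, with 3 counts over the whole group as the floor. CPM were computed with library sizes scaled by TMM factors and are given as mean ± SD over n = 3 libraries.

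Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the gene counts. Of 55401 genes in the table, 20744 passed filterByExpr and were tested. All 9 libraries entered 1 quasi-likelihood fit with a mean per group, no covariate and no pairing, and the common biological coefficient of variation was 0.227. The 3 comparisons were CKD vs control, CKD+sh-GALNT3 vs CKD and CKD+sh-GALNT3 vs control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold.

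Gene lists were tested with camera (limma 3.58.1) on the same fit with a preset correlation between genes of 0.01, and adjusted over 40 lists. Camera was repeated with a correlation estimated per list, and fry was run as a test of whether a list's own genes move one way on balance. The lists covered Galnt3 and the disease (GalNAc-transferase family, phosphate and vitamin D handling, urate and purine handling, TNF and NF-kB response, MAPK early response, matrix and fibrosis, EMT regulators and mesenchymal markers, tubule injury). They covered kidney cell types (proximal tubule, loop of Henle, distal convoluted tubule, collecting duct principal cell, intercalated cell, podocyte, endothelial cell, fibroblast and pericyte). They covered blood cells and neighbouring tissues (macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil, erythroid, adipocyte, adrenal cortex, skeletal muscle). The remaining lists were cell processes (fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrial genome, ribosomal proteins, interferon response, MHC class II, complement, apoptosis-promoting genes, ER stress, heat shock, antioxidant response, cell cycle, cholesterol synthesis, circadian clock, sex-dependent genes, renin and kallikrein). For each list, the number of members called is given over all genes tested and adjusted over the list alone.

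The groups, the tests, the 40 lists, the rule for naming genes and most alternatives were fixed before the data were examined. Under that rule, Galnt3 is named in each comparison. The rule also names the 10 higher and 10 lower called genes with the largest absolute log2 fold change (5 and 5 for CKD+sh-GALNT3 vs control), if all 3 libraries of one group lay on one side of the other 3, the higher group had a mean CPM of at least 1, the gene had at least 50 counts, and its symbol was not that of a predicted gene, clone, pseudogene or receptor segment. Chance alone puts 3 libraries wholly on one side of 3 others for 10% of genes. From each gene list described, up to 4 members with the smallest p are named, whether or not they passed. Some genes that meet the rule are not reported here, and they remain in the counts of called genes and in the list tests. Lists of heart-muscle, pancreas acinar and liver genes, the search for genes read almost only in controls, and the alternatives built on them were chosen after the data were seen.

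The fit was tested on counts simulated from the real means and library sizes. Changes were put into 67, 67 and 66 genes at 1.5-fold, 2-fold and 4-fold. It recovered 44.8%, 68.7% and 90.9% for CKD vs control (3.55% of calls false). For CKD+sh-GALNT3 the shares were 38.8%, 70.1% and 90.9% vs CKD (2.21%) and 40.3%, 65.7% and 89.4% vs control (7.80%). They do not carry over where 0 genes were called, since planted changes loosen the adjustment.

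Alternatives tried were DESeq2 size factors and upper-quartile scaling in edgeR, no low-count filter and a filter of CPM 1 in 3 libraries, DESeq2 1.42.0, and limma on log2 of the deposited FPKM plus 0.1 or plus 1. Further alternatives were a fit on only the groups compared, the replicate number as a block, robust dispersions, a minimum absolute log2 fold change of 1, removal of the 48 most counted genes (24.7% of all counts), and each library left out in turn. Transcript tables were used for Galnt3 and to count called transcripts. No library or gene in the tables was left out of the main comparisons apart from the low-count filter.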

Results

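Gene counts were compared across 9 mouse kidney libraries, 3 from controls, 3 from mice with CKD and 3 labelled CKD+sh-GALNT3. The control libraries held 57076639, 56042572 and 52720089 counts, the CKD libraries 64946105, 51832755 and 54109734, and the libraries labelled CKD+sh-GALNT3 53107203, 56591313 and 54216783. A count was seen for 24709 to 26127 genes per library. Transcripts of the mitochondrial genome took 16.0 ± 0.721% of the counts in controls, 15.8 ± 0.709% in CKD and 14.9 ± 0.422% in the libraries labelled CKD+sh-GALNT3 (SD, n = 3).

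Galnt3 encodes an enzyme that starts O-linked sugar chains by adding N-acetylgalactosamine to proteins, and its transcript is the target of the hairpin. Its level did not differ detectably between the 3 groups, so the libraries labelled CKD+sh-GALNT3 are named by their label only, and no direction is ascribed to a loss of Galnt3. Galnt3 (ENSMUSG00000026994) lies on the minus strand of chromosome 2, from 66082766 to 66124994. It had 4069, 3902 and 3165 counts in the control libraries, 3909, 3852 and 3699 in the CKD libraries, and 3790, 3700 and 4071 in the libraries labelled CKD+sh-GALNT3. In CPM this was 72.7, 67.2 and 59.7 in controls, 59.4, 74.0 and 70.8 in CKD, and 73.6, 64.3 and 74.5 in the libraries labelled CKD+sh-GALNT3, with means of 66.5 ± 6.53, 68.1 ± 7.68 and 70.8 ± 5.65 (SD, n = 3). Of its 4 annotated transcripts, the one with 11 exons and 3885 nucleotides held 99.6% of the counts.

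The log2 fold change of Galnt3 in CKD vs control was 0.03 (SE 0.10, 95% interval -0.20 to 0.26, edgeR adjusted p = 0.936). In CKD+sh-GALNT3 vs CKD it was 0.06 (SE 0.10, 95% interval -0.17 to 0.29, edgeR adjusted p = 0.954), and the interval allows a Galnt3 decrease of at most 11.3%. Against control it was 0.09 (95% interval -0.14 to 0.32, edgeR adjusted p = 0.790), which allows a decrease of at most 9.21%. The sign of the Galnt3 change rested on single libraries: CKD vs control was -0.04 without control 3 and -0.03 without CKD 2, and CKD+sh-GALNT3 vs CKD was -0.03 without CKD 1. With a term for the libraries lacking heart-muscle transcripts, an alternative chosen after the data were seen, Galnt3 in CKD+sh-GALNT3 vs CKD was -0.00061. A lower protein level, or a loss in a minority of cells, is not measured by these counts.

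**Figure D1:**
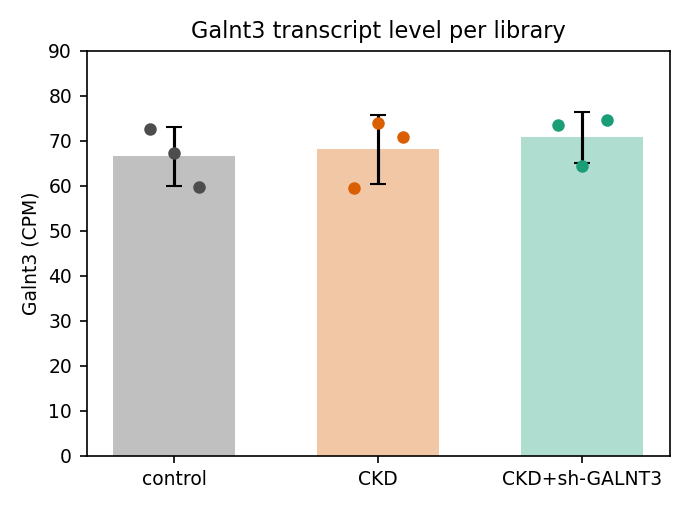
Galnt3 in CPM per library and group, with bars for the group means, error bars for the SD and points for the 3 libraries of each group. Group means lie at 66.5, 68.1 and 70.8 CPM, with the points of all groups between 59.4 and 74.5.

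CKD vs control asked which transcripts differ in the diseased kidney. Havcr1, whose protein (KIM-1) appears on injured proximal tubule cells, rose most of the genes named. Also higher were the growth factor gene Ccn2, the calcification inhibitor Mgp, the elastin cross-linking enzyme Loxl1, the matrix glycoprotein Adamtsl2 and the noncoding RNA Dnm3os, which carries microRNAs of mesenchymal cells. Cyp1b1, an enzyme that oxidises steroids and foreign compounds, Kynu, which breaks down kynurenines from tryptophan, Slc10a6, a carrier of sulphated steroids, and Clca3a1, a secreted regulator of chloride channels, rose as well.

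Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578) averaged 21.6 ± 20.8 CPM in CKD and 1.16 ± 0.147 in control (SD, n = 3), a log2 fold change of 4.21 (SE 0.72, edgeR adjusted p = 0.0363). Its CKD libraries lay far apart, at 44.3, 3.50 and 17.0 CPM, and without CKD 1 its log2 fold change was 3.14. Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) rose from 65.5 ± 2.47 to 127 ± 7.82 CPM, with a log2 fold change of 0.96 (SE 0.08, edgeR adjusted p = 0.000939). Mgp (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823) rose from 23.2 ± 1.25 to 52.03 ± 10.9 CPM (log2 fold change 1.16, SE 0.13, edgeR adjusted p = 0.00445), and Cyp1b1 from 23.6 ± 4.33 to 52.2 ± 8.29 CPM (1.14, SE 0.14, 0.00863). Loxl1 rose from 6.68 ± 1.80 to 14.2 ± 1.56 CPM (log2 fold change 1.08, SE 0.18, edgeR adjusted p = 0.0336) and Adamtsl2 from 9.16 ± 1.22 to 19.6 ± 4.49 CPM (1.09, SE 0.18, 0.0316). Dnm3os had a log2 fold change of 1.68 (SE 0.23, edgeR adjusted p = 0.0132) and Kynu one of 0.98 (SE 0.15, 0.0226). Slc10a6 (1.80, SE 0.34, edgeR adjusted p = 0.0492) and Clca3a1 (1.57, SE 0.29, 0.0457) passed narrowly. Over the fits that each left out 1 library, only Ccn2 and Mgp of these 10 genes stayed called throughout. The highest adjusted p of edgeR in those fits was 0.172 for Havcr1, 0.0780 for Cyp1b1, 0.0943 for Dnm3os, 0.123 for Kynu, 0.156 for Loxl1 and Adamtsl2, 0.182 for Clca3a1 and 0.183 for Slc10a6. Without control 1 or control 3, all of these 8 lost the call. Havcr1, Kynu, Adamtsl2, Clca3a1 and Slc10a6 also lost it without control 2, and all of the 8 except Havcr1 and Cyp1b1 lost it without CKD 2. Without CKD 3 it was lost by Havcr1, Kynu, Loxl1, Adamtsl2, Clca3a1 and Slc10a6, and without CKD 1 by Kynu, Loxl1, Clca3a1 and Slc10a6. Havcr1, Clca3a1 and Slc10a6 lost it without CKD+sh-GALNT3 2 or CKD+sh-GALNT3 3, and Slc10a6 also without CKD+sh-GALNT3 1.

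**Figure D2:**
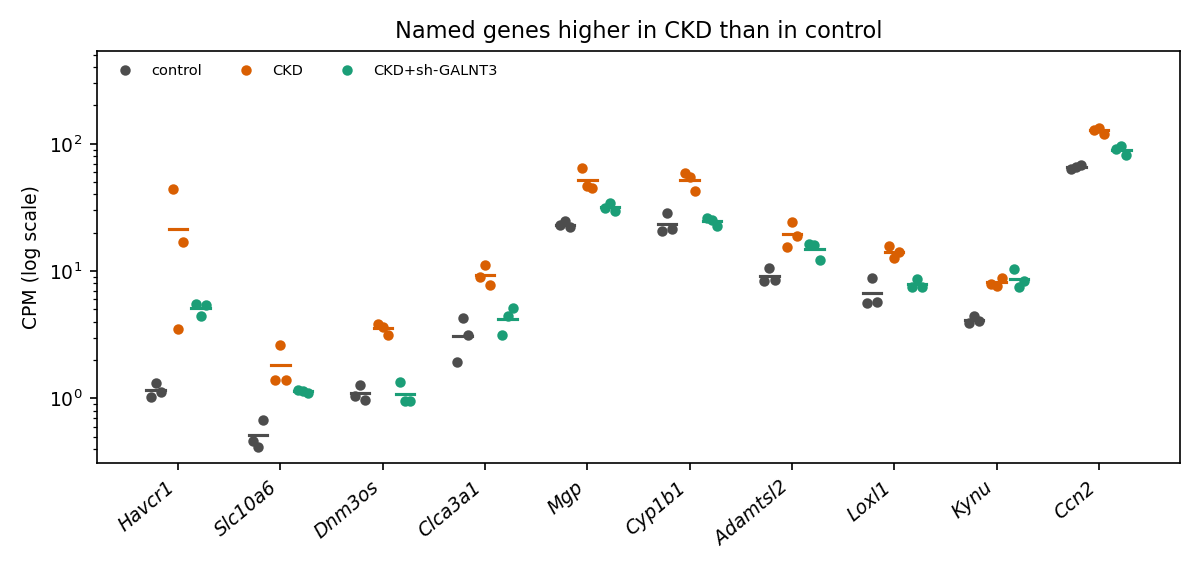
The 10 genes named as higher in CKD, in CPM on a log axis, with a point per library and a line at each group's mean. Ccn2 lies near 127 CPM in CKD against 65.5 in control, and Havcr1 spreads from 3.50 to 44.3 CPM within the CKD group.

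By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 33 genes were higher and 102 lower in CKD, 135 in all, and 97 of these had an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 2465 genes, where chance gives 1037. Of the higher genes 31, and of the lower genes 91, met the conditions for naming. The number called depended on single libraries: 29, 49 and 20 genes were called without control 1, control 2 and control 3, and 79, 55 and 87 without CKD 1, CKD 2 and CKD 3. Without CKD+sh-GALNT3 1, 154 genes were lower, and without CKD+sh-GALNT3 2 or 3, 20 genes were higher. With a term for the libraries that lacked heart-muscle transcripts, CKD 1 and CKD 2, 19 genes were called, 9 of them among the 135. With those libraries left out, 35 were called, 17 of them shared. Both alternatives were chosen after the data were seen. Upper-quartile scaling lowered the share of higher genes among the calls from 24.4% to 18.9%.

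Among the lower genes, Khdc1a and Khdc1c, neighbouring genes known from oocytes and early embryos, the protease inhibitors Serpinb9b and Serpinb7, the mucus peptide Tff2, the nucleoside carrier Slc28a3, the growth factor Bmp8b and the X-linked gene Pnma5 were read in all 3 controls and at or near 0 in CKD. Ptprtos, an RNA antisense to a phosphatase gene, had the same course. Nppa, the atrial natriuretic peptide of heart muscle, was lower too, and Xist, the RNA that silences an X chromosome in female cells, fell, while Y-linked genes were read in every group.

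Serpinb9b (ENSMUSG00000021403, chromosome 13, 33027416 to 33041884) fell from 10.5 ± 0.898 CPM in control to 0.181 ± 0.0777 in CKD (SD, n = 3), a log2 fold change of -5.86 (SE 0.52, edgeR adjusted p = 0.00121). Khdc1c was at least 81.4-fold lower (edgeR adjusted p = 0.0124), Bmp8b at least 65.3-fold (0.0481) and Ptprtos at least 58.4-fold (0.0372), since all their CKD libraries had 0 counts. Log2 fold changes were -6.18 for Slc28a3 (edgeR adjusted p = 0.0226), -6.16 for Khdc1a (0.0301), -5.93 for Tff2 (0.0484), -5.58 for Serpinb7 (0.0391) and -4.15 for Pnma5 (0.0124; -5.00 without CKD 1). Nppa fell from 5.87 ± 3.56 to 0.177 ± 0.232 CPM (log2 fold change -5.06, SE 0.95, edgeR adjusted p = 0.0492), and had -6.81 without CKD 3. Xist fell from 52.3 to 5.19 CPM (log2 fold change -3.33, SE 0.23, edgeR adjusted p = 0.000851), while the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y averaged 65.9, 26.4, 32.4 and 56.8 CPM in control and 77.2, 28.4, 37.3 and 64.1 in CKD. Khdc1a and Khdc1c are near copies that may share reads, and reads of Ptprtos may belong to the gene it overlaps, since the strand setting is not known. Xist and Serpinb9b stayed called whichever library was left out. The highest adjusted p of edgeR without 1 library was 0.0987 for Khdc1c, 0.137 for Khdc1a, 0.171 for Bmp8b, 0.184 for Ptprtos, 0.117 for Slc28a3, 0.165 for Tff2, 0.159 for Serpinb7, 0.149 for Nppa and 0.0819 for Pnma5, and each of these 9 was lost without control 1 or control 3. All but Pnma5 were also lost without control 2. Without CKD 1 the calls of Khdc1a, Bmp8b, Ptprtos, Tff2 and Nppa were lost, without CKD 2 those of Khdc1a, Bmp8b, Ptprtos, Slc28a3, Serpinb7 and Nppa, and without CKD 3 those of Bmp8b, Ptprtos, Slc28a3, Tff2 and Serpinb7. Bmp8b was lost without CKD+sh-GALNT3 2 or 3, and Nppa without CKD+sh-GALNT3 1 or 3.

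Genes of dividing cells fell in CKD. Tpx2 and Aurka build the mitotic spindle, Top2a untangles replicated DNA and Cenpf sits at the attachment sites of chromosomes, and all 4 were lower in CKD than in control. Tpx2 fell from 10.4 to 2.42 CPM (log2 fold change -2.10, SE 0.18, edgeR adjusted p = 0.00101), Top2a from 23.6 to 7.97 (-1.57, SE 0.17, 0.00343), Aurka from 5.49 to 1.58 (-1.79, SE 0.23, 0.00863) and Cenpf from 8.70 to 2.72 (-1.68, SE 0.21, 0.00863). In sum, the cell cycle genes took 249, 256 and 288 CPM in controls and 124 to 161 in the other 6 libraries. The same controls stood apart in other transcripts: neutrophil genes took 58.2 to 85.2 CPM there against 6.37 to 39.7 elsewhere, and 12 genes read almost only in controls, chosen after the data were seen, took 34.3 CPM. The cell cycle list had a median log2 fold change of -0.998 (camera adjusted p = 3.92e-38, adjusted p = 0.102 with an estimated correlation). Of its 27 genes, 10 were called lower over all genes and 21 when adjusted over the list alone. It was the only list called by fry (adjusted p = 0.00858). The list stayed called by camera whichever library was left out, as did Tpx2 and Top2a by edgeR, while without control 3 Aurka (edgeR adjusted p = 0.0610) and Cenpf (0.0623) were not called.

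**Figure D3:**
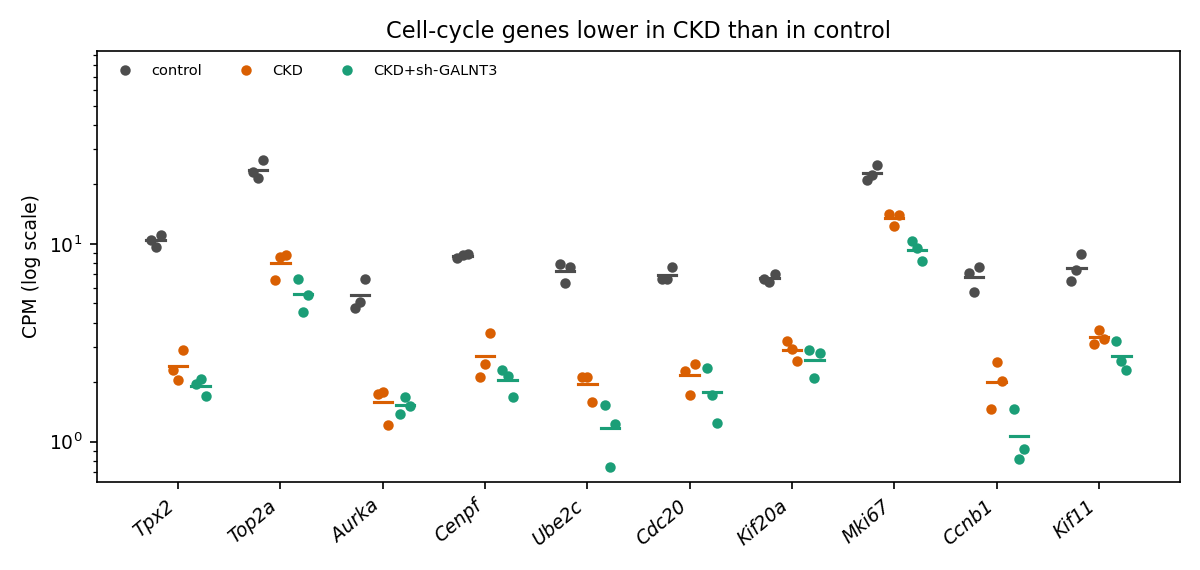
The 10 cell cycle genes called lower in CKD, in CPM on a log axis, with a point per library and a line at each group's mean. Control libraries lie above the CKD libraries for each gene, as for Tpx2 at a mean of 10.4 CPM against 2.42.

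Injury, matrix and inflammation genes went both ways in CKD. Of the tubule injury list, Havcr1 rose and Cd44, a receptor for hyaluronan on injured epithelium, fell, while the iron-oxidising plasma protein gene Cp and the cell cycle inhibitor Cdkn1a did not pass. Of the matrix and fibrosis list, Ccn2, Mgp and Loxl1 rose, whereas Fn1, the gene of fibronectin, fell. Vcam1 and Cx3cl1, which hold white blood cells to vessel walls, rose among the TNF and NF-kB response genes, while the chemokine genes Ccl2 and Cxcl5 did not pass and had opposite signs. Phlda1, an early target of growth signals, fell among the MAPK early response genes, and the growth regulator Myc did not pass.

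Cd44 fell from 24.0 to 11.7 CPM (log2 fold change -1.04, SE 0.13, edgeR adjusted p = 0.00973), Fn1 from 191 to 63.3 (-1.59, SE 0.22, 0.0124) and Phlda1 from 16.7 to 6.77 (-1.30, SE 0.20, 0.0235). Vcam1 rose from 16.5 to 29.6 CPM (log2 fold change 0.84, SE 0.14, edgeR adjusted p = 0.0368) and Cx3cl1 from 61.7 to 85.5 (0.47, SE 0.09, 0.0492). Not passing were Cp (log2 fold change 0.65, edgeR adjusted p = 0.0622), Cdkn1a (-0.76, 0.0651), Myc (-1.18, 0.0518), Ccl2 (-1.10, 0.0902) and Cxcl5 (1.32, 0.106). Cd44 was lost without control 1 or control 3 and Fn1 without control 1, control 3 or CKD 2 (highest edgeR adjusted p = 0.0780 for both). Phlda1 (highest edgeR adjusted p = 0.123) was lost without any 1 control, CKD 2 or CKD 3. Vcam1 (0.124) was called only without CKD+sh-GALNT3 1, and Cx3cl1 (0.172) in none of these fits. Of the genes that did not pass, Cp was called without CKD 3 (edgeR adjusted p = 0.0457), and Cdkn1a (0.0317) and Myc (0.00902) without CKD+sh-GALNT3 1.

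The tubule injury list fell on balance (median log2 fold change -0.31, camera adjusted p = 0.0215, adjusted p = 0.758 with an estimated correlation), with 1 member called higher and 1 lower, or 6 and 12 adjusted over the list alone. The MAPK early response list fell too (median -0.18, camera adjusted p = 0.0105, adjusted p = 0.662 with an estimated correlation), with 1 member lower, or 1 higher and 7 lower adjusted over the list alone. The TNF and NF-kB response list was not called (median -0.13, camera adjusted p = 0.463), with 2 members higher, or 4 higher and 6 lower adjusted over the list alone. The matrix and fibrosis list was not called either (median -0.05, camera adjusted p = 0.609), and camera put it in the upward direction although its median and mean were below 0. It had 3 members higher and 2 lower, or 6 and 3 adjusted over the list alone. The list of EMT regulators and mesenchymal markers had a median of -0.02 (camera adjusted p = 0.790). Without CKD 2, CKD 3 or control 3 the tubule injury list was not called (camera adjusted p = 0.762, 0.269 and 0.0771), and without CKD 2 camera's direction for it turned upward. Its summed CPM was 3021, 1620 and 2011 in CKD against 1743, 1810 and 1838 in control. The MAPK list was not called without CKD 2 or control 3 (0.148 and 0.0541).

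Along the nephron, Slc13a1, the sulphate carrier of the proximal tubule, rose, and genes of the collecting duct were lower as a group by camera (adjusted p = 0.662 with an estimated correlation), with 0 members called over all genes. Slc13a1 rose from 247 to 373 CPM (log2 fold change 0.59, SE 0.09, edgeR adjusted p = 0.0226), and was not called without any 1 control, CKD 1 or CKD 3 (highest edgeR adjusted p = 0.109). Fxyd4 and Aqp4, a regulator of the sodium pump and a water channel of the collecting duct, had log2 fold changes of -1.31 and -1.04 (edgeR adjusted p = 0.165 and 0.412), Aqp4 -0.43 without control 2. Foxi1, the factor that makes intercalated cells, had 0.54 (edgeR adjusted p = 0.0782), and Cyp27b1, which activates vitamin D, 1.11 (0.238). Without CKD+sh-GALNT3 1, Fxyd4 (edgeR adjusted p = 0.0484) and Foxi1 (0.0317) were called.

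The collecting duct principal cell list fell (median log2 fold change -0.19, camera adjusted p = 0.0103, adjusted p = 0.662 with an estimated correlation) and stayed called whichever library was left out. Medians of the other called lists were 0.10 for proximal tubule (camera adjusted p = 0.0313, adjusted p = 0.840 with an estimated correlation), -0.15 for loop of Henle (0.0489), 0.17 for distal convoluted tubule (0.0211), 0.26 for intercalated cell (0.0287) and 0.14 for phosphate and vitamin D handling (0.0473). Each of those last 4 had a camera adjusted p = 0.662 with an estimated correlation. Adjusted over the list alone, 1 proximal tubule gene was higher, 1 collecting duct gene was lower, and 3 intercalated cell genes were higher and 1 lower. These lists leaned on single libraries. Without CKD 3 or control 3, camera's adjusted p was 0.850 and 0.328 for proximal tubule, 0.310 and 0.262 for loop of Henle, 0.173 and 0.142 for distal convoluted tubule, 0.107 and 0.142 for intercalated cell, and 0.402 and 0.246 for phosphate and vitamin D handling. Without CKD 2, camera's adjusted p was 0.0681, 0.0765, 0.117, 0.0540 and 0.0540 for the same lists. Without control 2, proximal tubule (0.143) and phosphate and vitamin D handling (0.0723) were not called by camera, and loop of Henle was lost without CKD+sh-GALNT3 1 (0.0569) or CKD+sh-GALNT3 2 (0.0590). Not called were podocyte (median 0.10, camera adjusted p = 0.216), endothelial cell (-0.02, 0.899) and fibroblast and pericyte genes (0.01, 0.561, mean below 0).

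Immune lists differed in sign in CKD. Antigen presentation through MHC class II rose as a list, led by its regulator Ciita, and macrophage and T cell lists rose, while antiviral interferon response genes such as Irf7, Usp18 and Zbp1 fell as a list. None of the 4 lists was called with an estimated correlation (adjusted p = 0.662 to 0.758). None of these genes passed alone: Ciita had a log2 fold change of 1.00 (edgeR adjusted p = 0.0638), Irf7 -0.47 (0.137), Usp18 -0.92 (0.167), Zbp1 -0.63 (0.265), the macrophage lysozyme gene Lyz2 0.62 (0.275), Il7r, a cytokine receptor gene of T cells, 1.17 (0.302) and the antibody gene Ighm 0.95 (0.110). Without CKD 1, Ighm was called (edgeR adjusted p = 0.0304). The MHC class II list rose (median 0.37, camera adjusted p = 0.000491) and the interferon response list fell (median -0.31, camera adjusted p = 0.000491). Both had an adjusted p = 0.662 with an estimated correlation, and both stayed called by camera whichever library was left out. Adjusted over the list alone, 1 MHC class II gene was higher and 2 interferon genes were lower. Macrophage and monocyte genes rose (median 0.17, camera adjusted p = 0.0215, adjusted p = 0.758 with an estimated correlation), but not without CKD 1 (0.722) or control 3 (0.131). T and NK cell genes rose (median 0.31, camera adjusted p = 0.0385, adjusted p = 0.671 with an estimated correlation), but not without CKD 1 (0.151), CKD 2 (0.0551) or control 1 (0.601). B and plasma cell (median 0.23, camera adjusted p = 0.348), neutrophil (-0.29, 0.503) and complement genes (0.16, 0.0525) were not called, with 1, 0 and 2 members higher adjusted over the list alone.

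Stress genes differed in sign too. The heat shock list of chaperone genes rose (median log2 fold change 0.48, camera adjusted p = 2.16e-05, adjusted p = 0.662 with an estimated correlation) whichever library was left out, with 0 members called by edgeR over all genes and 4 higher adjusted over the list alone, and with log2 fold changes of 0.81 for Dnajb1 (edgeR adjusted p = 0.159), 0.83 for Hsph1 (0.251) and 0.49 for Hsp90aa1 (0.275). Trib3, a kinase-like brake induced when amino acids run short, fell from 6.34 to 1.13 CPM (log2 fold change -2.49, SE 0.35, edgeR adjusted p = 0.0142), and Chac1, which splits glutathione, did not pass (-1.22, 0.0758). Slc7a11, the cystine importer that feeds glutathione synthesis, fell from 6.44 to 1.01 CPM (log2 fold change -2.66, SE 0.33, edgeR adjusted p = 0.00827). Trib3 was lost without any 1 control (highest edgeR adjusted p = 0.0864) and Slc7a11 without control 3 (0.0604).

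Ribosomal protein genes fell (median log2 fold change -0.07, camera adjusted p = 0.0211, adjusted p = 0.840 with an estimated correlation), but not without CKD 2 (0.137), CKD 3 (0.107) or control 3 (0.474). Erythroid genes fell (median -0.62, camera adjusted p = 0.0215, adjusted p = 0.662 with an estimated correlation), but not without CKD 2 (0.0786), CKD 3 (0.310), control 2 (0.119) or control 3 (0.139). The lists not called had medians of 0.11 for ER stress (camera adjusted p = 0.846, mean -0.15, 1 member lower), 0.15 for antioxidant response (0.216, mean -0.01, 1 member lower), -0.04 for cholesterol synthesis (0.320, 1 member lower) and -0.15 for apoptosis-promoting genes (0.0686). Those for energy metabolism were 0.04 for fatty acid oxidation (camera adjusted p = 0.359), -0.04 for nuclear oxidative phosphorylation (0.463) and 0.02 for the mitochondrial genome (0.361). Medians were -0.02 for the GalNAc-transferase family (camera adjusted p = 0.815), 0.07 for urate and purine handling (0.740, mean -0.17), 0.08 for circadian clock (0.359), 0.05 for renin and kallikrein (0.970) and 0.17 for sex-dependent genes (0.124, mean -0.52, Xist lower). Among neighbouring tissues, adipocyte genes had a median of -0.89 (camera adjusted p = 0.740), adrenal cortex -0.0033 (0.727, with a sign that changed under another scaling) and skeletal muscle -0.07 (0.709). In these lists, adjusted over the list alone, 3 ER stress genes and 1 gene each of the antioxidant, cholesterol, apoptosis, adrenal, renin and sex-dependent lists were lower, and 1 circadian gene was higher.

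In all, camera called 16 of the 40 lists in CKD vs control, 8 higher and 8 lower, and 0 with an estimated correlation (smallest adjusted p = 0.102), against 1 by fry. Without control 3 or CKD 2, camera called 6 lists. Further lists were called with 1 library left out. Without control 2, matrix and fibrosis (camera adjusted p = 0.0175) and complement (0.00390) were called higher, and nuclear oxidative phosphorylation (0.0204) and apoptosis (0.0252) lower. Without CKD 1, TNF and NF-kB response (0.0306) and apoptosis (0.0174) were called lower, and without CKD 3 complement higher (0.0406) and sex-dependent (0.0406) and skeletal muscle genes (0.00431) lower.

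**Figure D4:**
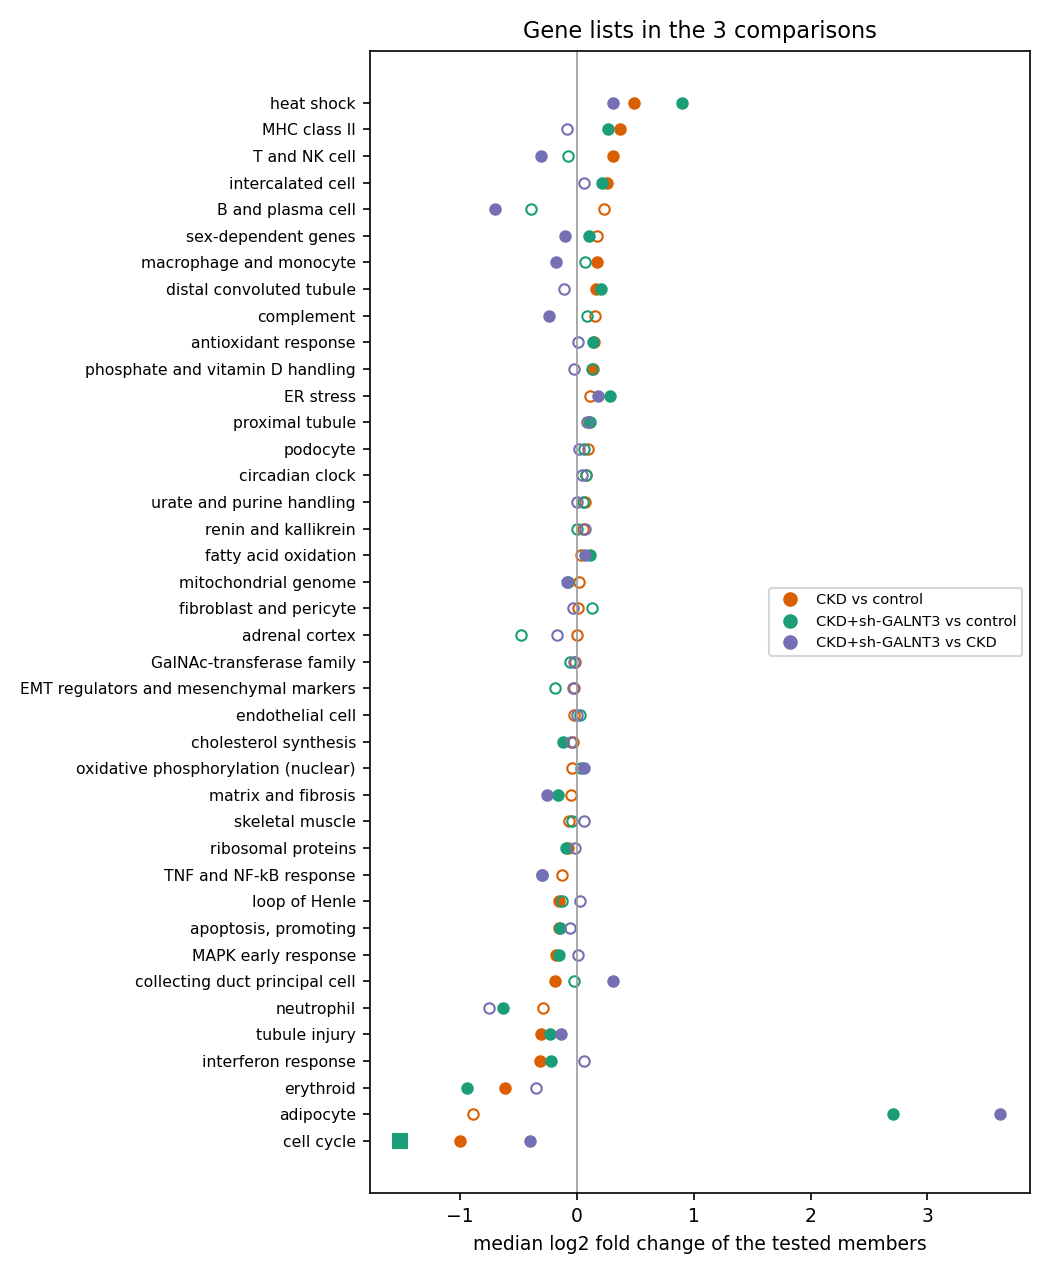
Median log2 fold change of the 40 gene lists in the 3 comparisons, with filled markers where camera's adjusted p was under 0.05 and a square where it was so with an estimated correlation too. Only the cell cycle list in CKD+sh-GALNT3 vs control, at -1.51, has a square.

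CKD+sh-GALNT3 vs CKD asked what differs with the hairpin or its delivery, as no group is labelled with a control hairpin. No gene passed, but gene groups shifted: genes of the TNF and NF-kB response, of matrix and of dividing cells fell as lists, and adipocyte, heat shock and collecting duct genes rose. These were calls by camera with its preset correlation: with an estimated correlation 0 of the 40 lists were called (smallest adjusted p = 0.360), and 0 by fry. The TNF response genes with the smallest p were the chemokine genes Cxcl5, Ccl2 and Ccl20 and the adhesion gene Vcam1. In the matrix list they were Ccn2, Mgp, Loxl1 and Fn1. All had negative fold changes.

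By edgeR's quasi-likelihood test, 0 genes were called, against 1418 at an unadjusted p under 0.05 where chance gives 1037, and the smallest adjusted p was 0.128, for Cyp1b1 and Cxcl5. DESeq2 called 28 higher and 57 lower, limma on log2(FPKM + 0.1) 1 higher and 0 lower, and limma on log2(FPKM + 1) 2 higher and 1 lower. Of transcripts, edgeR called 3 higher and 1 lower of 49047. Leaving out CKD 3 gave 23 calls, CKD+sh-GALNT3 1 gave 17, and CKD 1 or control 2 gave 1 each. With CKD 1 and CKD 2 left out there were 7 calls and with a term for the heart-muscle transcripts 4, both chosen after the data were seen. Those 4 genes, also chosen after their values were seen, were Mapkapk5, Adam1a, Gm13648 and Gm42878. They marked CKD 3 alone: Mapkapk5 was at 13.4 CPM in CKD 3 and 29.0 to 31.5 in the other libraries, and Adam1a at 31.1 in CKD 3 and 4.82 to 6.66 in the others, while Gm13648 and Gm42878 had 0 CPM in CKD 3.

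Cyp1b1 had a log2 fold change of -1.09 (SE 0.14, edgeR adjusted p = 0.128), and without CKD 3 it was called (0.00727). Cxcl5 averaged 2.28 CPM in the libraries labelled CKD+sh-GALNT3 and 10.6 in CKD (log2 fold change -2.22, SE 0.32, edgeR adjusted p = 0.128), Ccl2 2.10 and 5.77 (-1.46, SE 0.25, 0.297), Ccl20 0.194 and 1.18 (-2.61, SE 0.45, 0.297) and Vcam1 17.1 and 29.6 (-0.79, SE 0.14, 0.331). Without CKD+sh-GALNT3 1, Ccl20 was called (-3.33, edgeR adjusted p = 0.0259). The TNF and NF-kB response list fell (median -0.30, camera adjusted p = 8.85e-11, adjusted p = 0.360 with an estimated correlation), with 7 members lower adjusted over the list alone, and stayed called whichever library was left out. The MAPK early response list was not called (median 0.01, camera adjusted p = 0.939, with a median and mean of opposite sign), nor were EMT regulators and mesenchymal markers (median -0.03, 0.290).

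Ccn2 averaged 89.6 CPM in the libraries labelled CKD+sh-GALNT3 and 127 in CKD (log2 fold change -0.51, SE 0.08, edgeR adjusted p = 0.155), Mgp 31.7 and 52.03 (-0.71, SE 0.13, 0.325), Loxl1 7.90 and 14.2 (-0.84, SE 0.18, 0.437) and Fn1 35.8 and 63.3 (-0.82, SE 0.21, 0.552). The matrix and fibrosis list fell (median -0.26, camera adjusted p = 7.01e-08, adjusted p = 0.606 with an estimated correlation), with 5 members lower adjusted over the list alone, but not without CKD+sh-GALNT3 1 (0.568). Among tubule injury genes, Havcr1 had a log2 fold change of -2.08 (edgeR adjusted p = 0.670; -1.01 without CKD 1) and Cd44 one of -0.57 (0.507). The tubule injury list fell (median -0.13, camera adjusted p = 0.0217, adjusted p = 0.757 with an estimated correlation), but not without CKD 1 (0.965) or CKD+sh-GALNT3 1 (0.702), where camera's direction turned upward both times. Of the dividing-cell genes, Mki67 had a log2 fold change of -0.53 (edgeR adjusted p = 0.452), Cdk1 -0.87 (0.646), Ccnb1 -0.92 (0.666) and Top2a -0.52 (0.679). The cell cycle list fell (median -0.40, camera adjusted p = 1.18e-09, adjusted p = 0.360 with an estimated correlation), with 1 member lower adjusted over the list alone, whichever library was left out.

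The fat cell genes Adipoq, a hormone, Plin1, the coat of lipid droplets, and Car3, a carbonic anhydrase, had positive fold changes that did not pass, while their list rose (adjusted p = 0.606 with an estimated correlation). Adipoq averaged 15.0 CPM in the libraries labelled CKD+sh-GALNT3 and 0.691 in CKD (log2 fold change 4.42, SE 1.51, edgeR adjusted p = 0.689), Plin1 12.5 and 0.541 (4.48, SE 1.59, 0.704) and Car3 106 and 25.5 (2.05, SE 0.71, 0.692), which became 2.41, 2.04 and 0.57 without CKD+sh-GALNT3 2. The adipocyte list rose (median 3.62, camera adjusted p = 6.36e-06, adjusted p = 0.606 with an estimated correlation), with 9 members higher adjusted over the list alone, whichever library was left out. Its summed CPM was 746 in CKD+sh-GALNT3 2, against 74.6 and 162 in the other libraries of that label and 85.7, 69.7 and 75.8 in CKD.

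Collecting duct genes were higher as a group, with log2 fold changes of 1.17 for Fxyd4 (edgeR adjusted p = 0.670), 1.27 for the vasopressin-regulated water channel Aqp2 (0.689; 0.67 without CKD+sh-GALNT3 3) and 1.02 for Aqp4 (0.733). The collecting duct principal cell list rose (median 0.31, camera adjusted p = 0.000466, adjusted p = 0.360 with an estimated correlation), whichever library was left out. Its summed CPM was 421.5, 577 and 739 in the libraries labelled CKD+sh-GALNT3 and 439, 408 and 385 in CKD, so CKD+sh-GALNT3 1 lay within the CKD range. Of the chaperone genes none passed, with log2 fold changes of 0.31 for Bag3 (edgeR adjusted p = 0.708), 0.72 for Hspb1 (0.730) and 0.58 for Hsph1 (0.736), and in the ER 0.33 for Hsp90b1 (0.436), 0.29 for Pdia4 (0.704) and 0.40 for Hyou1 (0.708). The heat shock list rose (median 0.30, camera adjusted p = 4.09e-05, adjusted p = 0.606 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone, but not without CKD 1 (0.0770). The ER stress list rose (median 0.18, camera adjusted p = 0.00275, adjusted p = 0.606 with an estimated correlation), with 1 member higher adjusted over the list alone, but not without CKD 1 (0.460), CKD+sh-GALNT3 1 (0.146) or CKD+sh-GALNT3 3 (0.0505).

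Immune cell lists fell (adjusted p = 0.360 to 0.757 with an estimated correlation), with Ighm and Jchain of antibody-making cells at log2 fold changes of -0.84 and -1.06 (edgeR adjusted p = 0.581 and 0.584) and the macrophage genes Lyz2 and Itgam at -0.54 and -0.79 (0.714 and 0.723), Itgam at -0.20 without CKD 1. Medians were -0.70 for B and plasma cell (camera adjusted p = 0.0217, adjusted p = 0.360 with an estimated correlation) and -0.18 for macrophage and monocyte (0.0217, adjusted p = 0.757 with an estimated correlation). They were -0.31 for T and NK cell (camera adjusted p = 0.0217, adjusted p = 0.745 with an estimated correlation) and -0.24 for complement (0.0217, adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone, 2 B and plasma cell genes were lower. Without CKD 1, camera's adjusted p was 0.0770, 0.961, 0.148 and 0.148 for the same 4 lists, and its direction for macrophage and monocyte genes turned upward. Without CKD+sh-GALNT3 1 it was 0.146 for B and plasma cell, 0.489 for macrophage and monocyte and 0.279 for complement, and T and NK cell genes were lost without CKD+sh-GALNT3 2 (0.157).

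Mitochondrial genome genes fell (median -0.08, camera adjusted p = 0.0213, adjusted p = 0.757 with an estimated correlation), while nuclear oxidative phosphorylation genes rose (median 0.06, camera adjusted p = 0.0316, adjusted p = 0.981 with an estimated correlation). Fatty acid oxidation genes rose (median 0.07, camera adjusted p = 0.0325, adjusted p = 0.757 with an estimated correlation), and sex-dependent genes fell (median -0.10, camera adjusted p = 0.0217, adjusted p = 0.360 with an estimated correlation), with Xist lower adjusted over the list alone. By camera, the mitochondrial genome list was lost without CKD 1 (0.0821), CKD 3 (0.172) or CKD+sh-GALNT3 2 (0.314), oxidative phosphorylation without CKD 1 (0.737, with the direction turned downward), CKD+sh-GALNT3 1 (0.756) or CKD+sh-GALNT3 2 (0.180), and sex-dependent genes without CKD+sh-GALNT3 3 (0.165). Fatty acid oxidation was lost without CKD 1 (0.149), CKD 2 (0.340), CKD+sh-GALNT3 1 (0.515) or CKD+sh-GALNT3 2 (0.368).

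Not called were neutrophil (median -0.75, camera adjusted p = 0.0633), adrenal cortex (-0.17, 0.0657), cholesterol synthesis (-0.05, 0.177), proximal tubule (0.09, 0.269), intercalated cell (0.06, 0.275), apoptosis-promoting (-0.06, 0.355) and antioxidant response genes (0.0058, 0.388). The GalNAc-transferase family had a median of -0.03 (camera adjusted p = 0.939, mean 0.01), phosphate and vitamin D handling -0.03 (0.841) and urate and purine handling -0.0040 (0.939). Medians were -0.09 for MHC class II (camera adjusted p = 0.458), 0.06 for interferon response (0.767), -0.01 for ribosomal proteins (0.703), 0.03 for loop of Henle (0.767), -0.11 for distal convoluted tubule (0.841), 0.02 for podocyte (0.962) and 0.0031 for endothelial cell (0.893). They were -0.03 for fibroblast and pericyte (camera adjusted p = 0.939, mean 0.21), -0.35 for erythroid (0.767), 0.06 for skeletal muscle (0.939, mean -0.72, Tnnt3 lower adjusted over the list alone), 0.04 for circadian clock (0.767) and 0.07 for renin and kallikrein (0.841, mean -0.06). The signs of the MAPK, podocyte, endothelial and antioxidant medians changed under another scaling, and camera's direction was opposite to the median for urate, erythroid, podocyte, fibroblast, MAPK, skeletal muscle and renin genes. Camera called 16 of the 40 lists, 6 higher and 10 lower, and 0 with an estimated correlation, as did fry. Without CKD 1 it called 9, and without CKD+sh-GALNT3 1 it called 10. With 1 library left out, camera called further lists. Lower were neutrophil genes without CKD 3 (camera adjusted p = 0.00219), CKD+sh-GALNT3 2 (0.00927), CKD+sh-GALNT3 3 (0.000541) or control 1 (0.0212), distal convoluted tubule without CKD 1 (0.00701), MHC class II without CKD 2 (0.0205), cholesterol synthesis without CKD+sh-GALNT3 1 (0.0106) and ribosomal proteins without CKD+sh-GALNT3 3 (0.0340). Higher were proximal tubule without CKD 3 (0.000653) or CKD+sh-GALNT3 3 (0.000541), erythroid (0.00144) and interferon response genes (0.00701) without CKD 1, and fibroblast and pericyte without CKD+sh-GALNT3 1 (0.0386). Skeletal muscle was called lower without CKD 2 (0.0494) and higher without CKD 3 (0.00561).

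Whether the CKD changes ran the other way in the libraries labelled CKD+sh-GALNT3 was examined over all genes. Of the 33 genes higher in CKD, among them Havcr1, Ccn2 and Mgp, 27 had a negative fold change in CKD+sh-GALNT3 vs CKD, with medians of 0.69 in CKD vs control, -0.40 in CKD+sh-GALNT3 vs CKD and 0.42 in CKD+sh-GALNT3 vs control. Of the 102 lower genes, 38 had a positive fold change, with medians of -1.79, -0.13 and -1.84. Both comparisons share the CKD libraries, which alone pulls such values apart. The covariance of the log2 fold changes over 20744 genes was -0.12, against -0.08 in 20 simulations of unchanged groups, a difference of -0.04. With separate CKD libraries in each comparison it averaged -0.02 (range -0.04 to -0.0036 over 3 estimates). The correlation was -0.44 against a simulated -0.50, across genes, which are not independent replicates. A low-count filter of CPM 1 in 3 libraries moved the covariance to -0.07.

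CKD+sh-GALNT3 vs control asked how the kidneys with the hairpin label differ from healthy ones. Dividing-cell genes were lower again, as were fibronectin (Fn1), Cd44, the inflammatory mediators Ccl2, Ccl20, Cxcl2 and Csf2, and Xist. Higher were Ugt1a2, which attaches glucuronic acid to waste products, the esterase Ces1g, the lysozyme Lyz1, the mucin Muc19 and Henmt1, which stabilises small germ-cell RNAs. Chaperone genes (Hsph1, Dnajb1, Bag3 and, in the ER, Hsp90b1) rose. Havcr1, which rose most of the genes named in CKD vs control, did not pass here, whereas Ccn2 did. The controls were also the libraries with the 12 genes read almost only there (34.3 CPM in sum) and with the highest neutrophil sums.

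Of 307 genes called by edgeR, 98 were higher and 209 lower, 174 had an absolute log2 fold change of at least 1, and 96 higher and 186 lower met the conditions for naming. At an unadjusted p under 0.05 there were 2681 genes, where chance gives 1037. The number called was 135, 115 and 79 without control 1, control 2 and control 3, and 194, 153 and 135 without CKD+sh-GALNT3 1, 2 and 3. Without CKD 2, 52 genes were higher. Upper-quartile scaling lowered the share of higher genes among the calls from 31.9% to 22.03%. With CKD 1 and CKD 2 left out 244 genes were called, and with CKD+sh-GALNT3 2 left out as well 178, of which 211 and 135 were among the 307.

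Ces1g (ENSMUSG00000057074, chromosome 8, 93302369 to 93337308) rose from 11.9 ± 3.85 CPM in control to 39.3 ± 7.92 (SD, n = 3), a log2 fold change of 1.72 (SE 0.23, edgeR adjusted p = 0.00643). Ugt1a2 rose from 0.725 ± 0.189 to 10.9 ± 4.93 CPM (log2 fold change 3.91, SE 0.80, edgeR adjusted p = 0.0451), and its reads may be shared with other genes of the Ugt1a family, which have exons in common. Lyz1 (log2 fold change 3.03, edgeR adjusted p = 0.00859), Muc19 (2.92, 0.00724) and Henmt1 (2.12, 0.0305) rose from 0.137, 0.265 and 0.385 CPM. The lower genes were those of the controls again: Rhox5, an X-linked gene of the reproductive tract, was at least 158-fold lower (edgeR adjusted p = 0.0120), Khdc1a at least 150.2-fold (0.00976), Khdc1c at least 78.1-fold (0.00701), the milk protein gene Csn3 at least 60.6-fold (0.0218) and Ptprtos at least 56.0-fold (0.0226), each with 0 counts in all libraries labelled CKD+sh-GALNT3. Ces1g and Muc19 stayed called whichever library was left out. Without control 3, edgeR's adjusted p was highest for Lyz1 (0.0608), Khdc1a and Khdc1c (0.0567 for both) and Rhox5 (0.0627), which kept their calls in all other such fits. Ugt1a2 (highest edgeR adjusted p = 0.206), Henmt1 (0.138), Csn3 (0.0967) and Ptprtos (0.134) were lost without any 1 control, CKD+sh-GALNT3 2 or CKD+sh-GALNT3 3, and Ugt1a2 also without CKD+sh-GALNT3 1, CKD 1 or CKD 2, and Henmt1 also without CKD+sh-GALNT3 1.

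Tpx2 (log2 fold change -2.44, edgeR adjusted p = 0.000587), Top2a (-2.09, 0.000754), Ube2c (-2.64, 0.00193) and Mki67 (-1.29, 0.00109) fell, and the cell cycle list had a median of -1.51 (camera adjusted p = 3.29e-64, adjusted p = 0.0213 with an estimated correlation). Of its 27 genes, 18 were called lower over all genes and 24 adjusted over the list alone. Fry called this list and no other (adjusted p = 0.000952). Xist fell from 52.3 to 2.80 CPM (log2 fold change -4.22, SE 0.24, edgeR adjusted p = 0.000141). The sex-dependent list was called lower (camera adjusted p = 0.00204, adjusted p = 0.234 with an estimated correlation) through Xist alone, its median being 0.11. These genes and lists stayed called whichever library was left out.

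Fn1 fell from 191 to 35.8 CPM (log2 fold change -2.41, SE 0.22, edgeR adjusted p = 0.00109), and Cd44 had a log2 fold change of -1.60 (SE 0.14, 0.000816). Ccn2 rose from 65.5 to 89.6 CPM (log2 fold change 0.45, SE 0.08, edgeR adjusted p = 0.0198), while Mgp (0.45, 0.141) and Havcr1 (2.13, 0.194) did not pass. Gdf15, a stress hormone (-1.77, SE 0.29, edgeR adjusted p = 0.0182), and Cdkn1a (-0.78, SE 0.16, 0.0436) fell. The tubule injury list fell (median -0.23, camera adjusted p = 7.33e-05, adjusted p = 0.600 with an estimated correlation), with 3 members lower, or 5 adjusted over the list alone, and stayed called whichever library was left out. The matrix and fibrosis list fell (median -0.17, camera adjusted p = 0.00204, adjusted p = 0.641 with an estimated correlation), with 1 member higher and 2 lower, or 2 and 5 adjusted over the list alone, but not without CKD+sh-GALNT3 1 (0.303) or control 2 (0.127). Fn1 and Cd44 stayed called whichever library was left out. Ccn2 (highest edgeR adjusted p = 0.0859) and Gdf15 (0.0933) were lost without any 1 control, CKD+sh-GALNT3 1 or CKD+sh-GALNT3 2, and Cdkn1a (0.150) in every such fit but that without CKD 1. Without CKD 2, Havcr1 was called (edgeR adjusted p = 0.0200), and without CKD 1 Mgp was (0.0255).

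Ccl2 fell from 12.4 to 2.10 CPM (log2 fold change -2.56, SE 0.26, edgeR adjusted p = 0.00193), Ccl20 from 2.07 to 0.194 (-3.41, SE 0.46, 0.00693), Cxcl2 from 1.70 to 0.424 (-2.00, SE 0.33, 0.0180) and Csf2 from 1.01 to 0.0259 (-5.23, SE 1.04, 0.0402). The TNF and NF-kB response list fell (median -0.30, camera adjusted p = 1.93e-08, adjusted p = 0.238 with an estimated correlation), with 4 members lower, or 7 adjusted over the list alone, whichever library was left out. Phlda1 (log2 fold change -1.31, edgeR adjusted p = 0.0138) and Myc (-1.14, 0.0402) fell in the MAPK early response list, whose median was -0.15 (camera adjusted p = 0.00770, adjusted p = 0.600 with an estimated correlation), with 3 members lower, or 1 higher and 8 lower adjusted over the list alone. That list was lost without CKD+sh-GALNT3 2 (camera adjusted p = 0.0688). Ccl2 and Ccl20 stayed called whichever library was left out. Cxcl2 was lost without control 1, control 3, CKD+sh-GALNT3 1 or CKD+sh-GALNT3 3 (highest edgeR adjusted p = 0.0910), Phlda1 without control 3 or CKD+sh-GALNT3 2 (0.0743), and Csf2 (0.150) and Myc (0.159) without any 1 control, CKD 2, CKD 3, CKD+sh-GALNT3 2 or CKD+sh-GALNT3 3.

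Hsph1 (log2 fold change 1.41, SE 0.27, edgeR adjusted p = 0.0349), Dnajb1 (1.07, SE 0.22, 0.0456), Bag3 (0.66, SE 0.11, 0.0222) and Hsp90b1 (0.42, SE 0.07, 0.0183) rose, while the amino acid response genes Trib3 (-2.97, SE 0.36, 0.00542), Chac1 (-1.75, SE 0.27, 0.0123) and Asns (-1.31, SE 0.25, 0.0319) fell. The heat shock list rose (median 0.90, camera adjusted p = 3.18e-14, adjusted p = 0.234 with an estimated correlation), with 3 members higher, or 9 adjusted over the list alone, whichever library was left out. The ER stress list rose (median 0.28, mean -0.06, camera adjusted p = 0.00870, adjusted p = 0.600 with an estimated correlation), with 1 member higher and 3 lower, or 10 and 3 adjusted over the list alone, but not without CKD+sh-GALNT3 1 (0.0525). Slc7a11 (log2 fold change -3.35, SE 0.34, edgeR adjusted p = 0.00193) fell, Bcl2l11, a trigger of cell death, fell (-0.76, SE 0.15, 0.0356), and the clock gene Per2 rose (0.71, SE 0.12, 0.0182). Slc7a11 and Trib3 stayed called whichever library was left out. The highest adjusted p of edgeR was 0.157 for Hsph1, 0.180 for Dnajb1, 0.0936 for Bag3, 0.104 for Hsp90b1, 0.0680 for Chac1, 0.134 for Asns, 0.133 for Bcl2l11 and 0.0910 for Per2. Without control 2 or control 3 all 8 were lost, without control 1 or CKD+sh-GALNT3 1 all but Chac1 and Per2, and without CKD+sh-GALNT3 3 all but Chac1. Dnajb1, Hsp90b1, Chac1 and Asns were lost without CKD+sh-GALNT3 2, and Hsph1 and Dnajb1 without CKD 2.

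Lists with fewer called genes had medians of 0.21 for intercalated cell, in which Foxi1 rose (log2 fold change 0.59, edgeR adjusted p = 0.0379; camera adjusted p = 0.00204, adjusted p = 0.234 with an estimated correlation), and -0.15 for apoptosis-promoting genes (camera adjusted p = 0.00739, adjusted p = 0.399 with an estimated correlation). Foxi1 was called only without CKD+sh-GALNT3 1 among the fits with 1 library left out (highest edgeR adjusted p = 0.139). MHC class II genes rose (median 0.26, camera adjusted p = 0.00688) and interferon response genes fell (-0.23, 0.00204), both with an adjusted p = 0.600 with an estimated correlation. Proximal tubule genes rose (median 0.12, camera adjusted p = 0.00204, adjusted p = 0.641 with an estimated correlation), as did distal convoluted tubule (0.21, 0.0303), fatty acid oxidation (0.12, 0.00739) and adipocyte genes (2.71, 0.00204), these 3 with an adjusted p = 0.600 with an estimated correlation. Ribosomal protein genes fell (median -0.09, camera adjusted p = 0.00356, adjusted p = 0.641 with an estimated correlation), as did cholesterol synthesis (-0.12, 0.0223, adjusted p = 0.600 with an estimated correlation), neutrophil (-0.63, 0.0303, adjusted p = 0.534 with an estimated correlation) and erythroid genes (-0.94, 0.0485, adjusted p = 0.625 with an estimated correlation). Antioxidant response genes rose (median 0.13, mean -0.01, camera adjusted p = 0.0292, adjusted p = 0.479 with an estimated correlation). Intercalated cell, apoptosis and MHC class II lists stayed called whichever library was left out. By camera, adipocyte genes were lost without CKD+sh-GALNT3 2 (0.304), interferon response without CKD+sh-GALNT3 1 (0.0611), proximal tubule without CKD+sh-GALNT3 1 (0.285), distal convoluted tubule without CKD+sh-GALNT3 2 (0.0991) or control 3 (0.198), and ribosomal proteins without CKD+sh-GALNT3 2 (0.180) or control 3 (0.206). Fatty acid oxidation was lost without CKD+sh-GALNT3 1 (0.0721), CKD+sh-GALNT3 2 (0.131) or control 2 (0.264), antioxidant response without CKD+sh-GALNT3 1 (0.179) or control 2 (0.113), cholesterol synthesis without CKD+sh-GALNT3 3 (0.282) or control 1 (0.125), and neutrophil without CKD+sh-GALNT3 1 (0.0986) or control 3 (0.0513). Erythroid genes were lost without CKD 2 (0.0535), CKD+sh-GALNT3 1 (0.0721), CKD+sh-GALNT3 2 (0.186), control 2 (0.247) or control 3 (0.198).

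Not called were the GalNAc-transferase family (median -0.06, camera adjusted p = 0.774), phosphate and vitamin D handling (0.13, 0.0940), urate and purine handling (0.05, 0.690, mean -0.20), EMT regulators and mesenchymal markers (-0.19, 0.226), loop of Henle (-0.13, 0.117), collecting duct principal cell (-0.02, 0.941, mean 0.04) and podocyte genes (0.06, 0.217). Also not called were macrophage and monocyte (0.07, camera adjusted p = 0.657), T and NK cell (-0.08, 0.785), B and plasma cell (-0.40, 0.479), complement (0.08, 0.845), adrenal cortex (-0.48, 0.110) and skeletal muscle genes (-0.05, 0.540). The remaining medians were 0.13 for fibroblast and pericyte (camera adjusted p = 0.495), 0.03 for nuclear oxidative phosphorylation (0.479), -0.08 for the mitochondrial genome (0.438), 0.08 for circadian clock (0.178), 0.03 for endothelial cell (0.941) and 0.0032 for renin and kallikrein (0.785), and the last 2 changed sign under another scaling. Camera's direction was opposite to the median for T and NK cell and renin genes. The lists without a called gene named above had 1 called lower each in cholesterol synthesis, antioxidant response (Slc7a11), adrenal cortex and skeletal muscle. Adjusted over the list alone, higher and lower genes were 2 and 0 in the intercalated cell and proximal tubule lists, 1 and 0 in MHC class II, distal convoluted tubule and phosphate and vitamin D handling, and 1 and 1 in urate and purine handling. They were 0 and 2 in apoptosis, 0 and 3 in interferon response, 0 and 1 in ribosomal proteins, adrenal cortex and skeletal muscle, 1 and 2 in cholesterol synthesis, 3 and 1 in antioxidant response, and 2 and 1 in circadian clock. Camera called 21 of the 40 lists, 9 higher and 12 lower, against 1 with an estimated correlation and 1 by fry, and between 16 and 22 with 1 library left out. Further lists called in such fits were, without CKD+sh-GALNT3 1, fibroblast and pericyte (camera adjusted p = 0.0174) and podocyte genes (0.0256) as higher and loop of Henle (0.0243) as lower, without CKD+sh-GALNT3 2 circadian clock as higher (0.0379), and without CKD 2 adrenal cortex (0.0406) and without control 2 the mitochondrial genome (0.0127) as lower. Nuclear oxidative phosphorylation and phosphate and vitamin D handling were called higher without CKD+sh-GALNT3 3 (0.0182 and 0.0200) or control 1 (0.0130 and 0.0166).

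CKD and the libraries labelled CKD+sh-GALNT3 were lower than control in many of the same genes. Of the 102 and 209 genes lower than control, 85 were shared, among them Xist, Tpx2 and Fn1, where independent lists would share 1.03. Of the 33 and 98 higher genes, among them Ccn2, 10 were shared, where independent lists would share 0.156. Both comparisons use the same controls, which alone raises the sharing, so independent lists are too low a reference. Unchanged groups simulated against the same controls shared 0.05 genes in each direction. Such groups give hardly any calls, so that value is no reference for lists of these lengths. The covariance of the log2 fold changes was 0.20 against a simulated 0.08, a difference of 0.12. With separate control libraries in each comparison it averaged 0.12 (range 0.10 to 0.15).

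Transcripts of other tissues and of blood cells were read in several libraries. Heart-muscle genes, summed over a list of 20 chosen after the data were seen, took 186, 191 and 210 CPM in controls, 17.5, 17.0 and 185 in CKD, and 187, 194 and 162 in the libraries labelled CKD+sh-GALNT3. The heart myosin gene Myh6 was at 1.82 and 1.48 CPM in CKD 1 and CKD 2 and at 26.3 to 45.6 CPM in the other 7 libraries. Nppa, named above as lower in CKD, belongs to this list. Pancreas acinar genes were highest in CKD 2 and CKD+sh-GALNT3 2, at 344 and 281 CPM, against 46.1 to 149.5 CPM elsewhere, and liver genes lay between 135 and 250.0 CPM. Erythroid genes lay between 63.6 and 385 CPM. Neutrophil genes summed to 58.2, 58.6 and 85.2 CPM in controls, 39.7, 29.9 and 12.6 in CKD, and 6.37, 15.3 and 39.0 in the libraries labelled CKD+sh-GALNT3. CKD 1 had the highest sum of tubule injury genes (3021 CPM) and the most Havcr1.

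**Figure D5:**
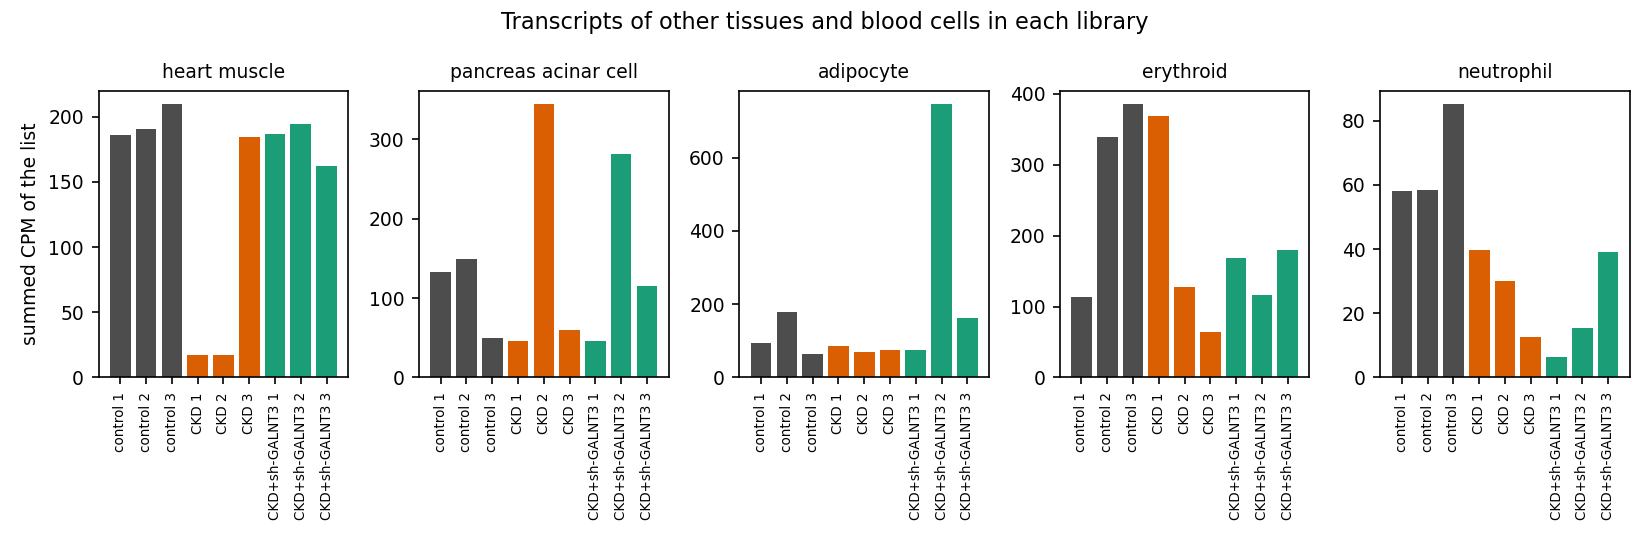
Summed CPM of heart-muscle, pancreas acinar, adipocyte, erythroid and neutrophil genes, with a bar per library. Heart-muscle bars fall to 17.5 and 17.0 CPM in CKD 1 and CKD 2, and the adipocyte bar of CKD+sh-GALNT3 2 stands at 746 CPM.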

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

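The term for heart-muscle transcripts and the fits without libraries in doubt were tests chosen after the results were seen, and the other alternatives were planned.

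The 123 results for single genes, Xist, Tpx2 and Ccn2 among them, gave 2825 values over 23 alternatives. Of these, 2337 kept their direction and side of the threshold, 437 kept the direction but lost the call, 51 gained one, and 0 changed direction with a call. The Galnt3 fold change stayed between 0.0039 and 0.09 in CKD vs control, 0.04 and 0.07 in CKD+sh-GALNT3 vs CKD, and 0.05 and 0.16 in CKD+sh-GALNT3 vs control, apart from the fits below. No scaling moved the median of all genes by over 0.1 (range -0.04 to 0.0042).

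Counts of called genes are given as higher and lower, in the order CKD vs control, CKD+sh-GALNT3 vs CKD and CKD+sh-GALNT3 vs control, and were 33 and 102, 0 and 0, and 98 and 209. DESeq2 called 243 and 384, 28 and 57, and 419 and 477. Limma called 15 and 135, 1 and 0, and 43 and 219 on log2(FPKM + 0.1), and 20 and 189, 2 and 1, and 46 and 253 on log2(FPKM + 1). Upper-quartile scaling called 63 higher and 223 lower in CKD+sh-GALNT3 vs control. With no low-count filter, 17 genes were higher in CKD vs control and 55 in CKD+sh-GALNT3 vs control. With only the 2 groups compared in the fit, 173 genes were lower in CKD vs control. The cause of these differences was not tested. Requiring an absolute log2 fold change of at least 1 left 10 higher genes in CKD vs control and 14 in CKD+sh-GALNT3 vs control, by its construction. DESeq2 size factors, the stricter filter, robust dispersions and removal of the most counted genes stayed within 1.5 times of each count.

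With the replicate number as a block, 8 genes were higher and 37 lower in CKD vs control, and 20 and 89 in CKD+sh-GALNT3 vs control, of which 43 of 45 and 108 of 109 were also called without it, and 0 in CKD+sh-GALNT3 vs CKD. The block changed no direction of Galnt3 and called 17, 15 and 20 lists. The numbers did not pair the libraries: 1 of 9 same-numbered pairs deviated together by a correlation over 0.1 (range -0.09 to 0.18), and 4 of 9 libraries correlated best with their own number.

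With the term for heart-muscle transcripts, 4 genes were higher and 15 lower in CKD vs control, 3 and 1 in CKD+sh-GALNT3 vs CKD and 86 and 203 in CKD+sh-GALNT3 vs control, and Galnt3 in CKD+sh-GALNT3 vs CKD was at -0.00061. With CKD 1 and CKD 2 left out, they were 5 and 30, 6 and 1, and 58 and 186, and Galnt3 was at -0.0011. With CKD+sh-GALNT3 2 left out as well, they were 4 and 37, 7 and 1, and 45 and 133. In all 3, CKD 3 alone carries the CKD level, so fewer libraries stand behind each comparison with CKD, and the lone CKD library is assumed to vary like the other groups.

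Leaving out each library in turn, the genes called higher and lower ranged from 2 to 34 and 17 to 154 in CKD vs control, 0 to 22 and 0 to 6 in CKD+sh-GALNT3 vs CKD, and 10 to 89 and 69 to 201 in CKD+sh-GALNT3 vs control. The fewest genes in all, 20 in CKD vs control and 79 in CKD+sh-GALNT3 vs control, came without control 3. Galnt3 ranged from -0.039 to 0.12, -0.033 to 0.12 and 0.02 to 0.16. The lists called by camera ranged from 6 to 17, 9 to 18 and 16 to 22. Of the 33 called genes named in CKD vs control, 6 were called in all 9 of these fits, Ccn2, Mgp, Serpinb9b, Top2a, Tpx2 and Xist, and of the 37 in CKD+sh-GALNT3 vs control, 13 were. All kept their sign.

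The lists called by camera, 16, 16 and 21, became 0, 0 and 1 with an estimated correlation and 1, 0 and 1 by fry, which asks another question. The covariance of the CKD change with the change in CKD+sh-GALNT3 vs CKD, -0.12, became -0.025 with disjoint CKD libraries, a fit that removes the shared error by construction, and -0.068 with the strict low-count filter, and ranged from -0.19 to -0.12 with a library left out. The cause of the last 2 was not tested. Depth limits the genes near the floor of 0.0462 to 0.0579 CPM, such as Khdc1c or Csf2, whose folds are bounds or have wide errors.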

Other observations

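The tests of the control-only genes, the heart-muscle source, the heart-muscle term and Galnt3 were chosen after the results were seen, and the splits were planned.

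The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In CKD vs control, where Xist and Ccn2 led, the labelled split was the 1 with 135 genes, and the highest other called 1. In CKD+sh-GALNT3 vs CKD, all 10 called at least the 0 of the labelled split, and the highest other called 1. In CKD+sh-GALNT3 vs control the labelled split was the 1 with 307 genes, and the highest other called 9.

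A set of 12 genes was read almost only in the control libraries, at 20 or more times the level of the other 6 and a mean of at least 1 CPM: Khdc1a, Khdc1c, Gm45336, Slc28a3, Tff2, Serpinb7, Serpinb9b, Ptprtos, Csn3, Pnma5, Fosl1 and Rhox5. They summed to 34.3 CPM in controls, 8 of them were called in CKD vs control, and Xist was lower outside the controls as well. Female controls are argued against, since 4 Y-linked genes stood at a median of 87.7% of their CKD level (range 85.5% to 92.8%). Normalization was not tested: with library sizes within 1.28-fold, genes chosen at 20-fold keep a high unscaled fold (lowest 21.8, 95% exact bound 15.0). RNA from 1 outside source shared by the controls stays open: the genes varied less between controls than level-matched genes, with a ratio of spreads of 0.516 (95% interval 0.410 to 0.932). The ratio was 0.534 for 8 genes at 50-fold but 1.45 for 27 genes at 10-fold, and the controls and any batch of theirs cannot be told apart. The disease itself, the difference the design names, was not tested apart from the groups. Nor was an outside source tested for the dividing-cell, Fn1 and inflammatory genes that were also highest in controls.

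Heart-muscle transcripts were read in 7 of 9 libraries and nearly absent from CKD 1 and CKD 2. A rule of at least 10 times the level of the other 2 in the lowest of the 7 was met by 10 of the 20 list genes, such as Myh6. Nppb met it only because it had 0 counts in the other 2 and in the lowest of the 7. Carry-over from 1 heart source stays open: the ratio of Nppa to Myh6 counts ran from 1.14% to 36.4%, 31.9-fold (95% exact interval 19.2 to 55.7, counting error only), and all 10 genes set against Myh6 differed beyond counting error (largest chi-square p = 0.000108), 5 of them over 2-fold, but their median was 1.88-fold, and the noise between library preparations is not known. Heart tissue taken with each kidney may also differ in its atrial share, as Nppa is an atrial gene, and this was not tested. A split of the CKD group that hides changes between CKD+sh-GALNT3 and CKD stays open: a term for it gave 4 called genes, all marking CKD 3, but the term leaves CKD 3 alone to carry the CKD level, and it also took CKD vs control from 135 called genes to 19. The design names no group that would bring heart transcripts, so no biological explanation was tested.

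Galnt3 was not lower in the libraries labelled CKD+sh-GALNT3. Too little precision to see a halving is argued against, since the 95% interval of the log2 fold change ended at -0.17. So is a swapped library with halved Galnt3, as the lowest had 79.7% of the highest, but other swaps would not show. A hairpin that acted in few cells, on the protein, or not at all could leave such counts, and the hairpin, the difference the design names, was not tested apart from its label.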
